A study of Arabidopsis thaliana with 54 samples.

How the data were processed

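Total RNA from infiltrated leaves was amplified, labelled with 1 dye and hybridised to 1 array per sample, per the labels' protocols. The 54 arrays comprise 9 accessions, each with 3 mock and 3 inoculated arrays, and the labels assign 1 array of every group to each of 3 sets that they call experiments. The labels do not state that the arrays of a group came from separate plants or pots, so p-values measure the spread between these arrays.

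The deposited values were taken as log2 intensities and used as deposited. Neither the log base nor the normalization is given in the sources used here. The values run from -0.64 to 16.53. The top values exceed 11.09, the natural log of the largest reading of a 16-bit scanner, and base 2 was assumed from that. The highest also exceeds 16.0, the log2 of the same reading, so the scanner limit does not settle the base. Array medians run from 3.25 to 4.85, so the authors' values were not centred on the median, and 30.4% of values recur to 9 decimals on another array. Mock arrays have medians between 3.25 and 4.44 and inoculated arrays between 4.25 and 4.85. If the base were another, the log differences would be multiplied by 1 common factor, the folds would be other numbers, and the limma tests would not change. Background and saturation flags were not used here.

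The table holds 576 probes, of which probe 231 is empty on all arrays, leaving 575. The platform annotation gives a single gene for 181 probes (180 of those tested) and several genes for 0, and 395 tested probes are unnamed here. Symbols were updated through gene identifiers in a RefSeq table of the TAIR10.1 assembly, which matched 180 of the 181, and 1 name was kept as given. No build is given in the sources used here, so no coordinates are printed. Each named gene has 1 probe.

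Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on a model with 18 group means over all 54 arrays, with Benjamini-Hochberg adjustment over 575 genes within each comparison and a threshold of 0.05. The comparisons were the mean over accessions of inoculated minus mock, the same within each accession, a moderated F-test of its difference among accessions, each accession against the mean of the other 8 (comparisons that share arrays), and a moderated F-test among the mock groups. Errors of differences are the moderated SE. The response size of an accession is the slope through the origin, over all genes and within each set, of its log2 difference on the mean response of the other 8. It was tested by shuffling accession labels within sets. The relation to the mock level of the salicylic acid list was tested over all 362880 orders of the 9 accessions. Gene lists with at least 3 measured genes were tested with fry, adjusted over lists. Fry tests whether the genes of a list move, on balance, one way, and does not compare the list with other genes. Camera does, but against an array of chosen genes.

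The genes to be named were chosen by a rule fixed before the data were examined, applied to the named probes. It takes the 10 largest rises and 10 largest falls with the same sign in all 9 accessions, the 10 largest F values for response and for mock level, up to 3 genes per accession with the largest difference from the other 8, and up to 4 members of each list. Of the 10 largest over all probes, 4 rises, 2 falls, 3 response F values and 4 mock F values belonged to named probes. The members of the 12 groups formed from gene names, and the comparisons of one accession's mock or inoculated level with the other 8, were not part of that rule.

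Arrays of the same set deviated together from their group means, with a mean correlation of 0.34 against -0.17 between sets, and the correlation of the mock and inoculated array of a pair was over 0.1 in 26 of 27 pairs (range -0.02 to 0.57). The set is a shared experiment in the labels, so the set numbers were taken to pair the arrays. The fit without a block had been fixed as the one reported, and for the genes, gene counts and fixed lists reported, values with the block are given where they change a call or move a count by over 1.5 times. No 2 arrays had identical values. The lowest correlation between replicates was 0.851 and the median 0.943.

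The fits were tested on simulated data with the 575 probes and 200 genes changed per run. For the mean over accessions, 88.8% of genes changed by 0.5 on the log2 scale and 98.4% of those changed by 1 were called. For a change in Col-0 alone, the test within Col-0 called 12.9%, 50.5% and 93.6% at 0.5, 1 and 2, the test against the other 8 called 11.9%, 46.6% and 91.6%, and the F-test called 1.4%, 12.9% and 73.1%. At most 1.92% of unchanged genes were called. The simulated noise was independent between arrays, without shared deviations within a set and without differences in mock level between accessions. These rates therefore need not hold in the data.

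The alternatives were median centring, quantile normalization, scaling to EF1A, leaving out the probes with the lowest mean levels, the set or the pair as a replicate block, a trended and robust variance model, each set alone or left out, single arrays left out, each accession's 6 arrays alone, the 27 mock arrays alone, camera, and other gene choices for the response size. Averaging probes of a gene changes nothing here, a pseudocount does not apply to log values, and PR1 alone could not be used because it is not among the named probes.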

Results

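Gene expression was measured in leaves of 9 Arabidopsis thaliana accessions, 6 h after infiltration with water (mock) or with Pseudomonas syringae pv. tomato carrying the effector gene avrRpt2 (Pst, 1e8 cfu/ml). RPS2 is the plant resistance protein whose activation follows recognition of the AvrRpt2 effector, and the series title names natural variation in RPS2-mediated resistance as its subject. The accessions, which are natural inbred lines collected from different places, were Ws-2, Col-0, Kas-1, Est-1, Mt-0, Ler-0, Kin-0, Cvi-1 and Tsu-1, and the plants were 4 weeks old. Each of the 18 combinations of accession and treatment was measured on 3 arrays, 1 in each of 3 sets, giving 54 arrays and 27 pairs of mock and inoculated arrays. Of 576 probes, 575 had values, and 180 of these carry a gene name here. Arrays give no read depth, and the 3 arrays per group limit the precision of every value below. The named probes do not include RPS2, RIN4, NDR1 or PR1.

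The first comparison asked which genes responded to the bacteria on average over the 9 accessions. UGT76B1 (AT3G11340), a glucosyltransferase that acts on salicylic acid, rose most among the named genes, from a mean log2 level of 3.63 in mock leaves to 8.94 after inoculation, a difference of 5.31 ± 0.23 (SE) or 39.6-fold if the values are to base 2. AT4G39670, of the glycolipid transfer protein family, rose by 4.68 ± 0.13, the heat shock protein gene Hsp70-2 (AT5G02490) by 4.44 ± 0.14, and GRX480 (AT1G28480), a glutaredoxin that binds TGA transcription factors, by 4.41 ± 0.16. The other 6 of the 10 largest rises were AT5G60800, a heavy metal-associated domain protein, by 4.10, AT2G32150, a haloacid dehalogenase-like hydrolase, by 3.83, AT2G28400 by 3.55, the chitinase family gene CHI (AT2G43570) by 3.5, AT1G26380, a berberine bridge enzyme-like oxidoreductase, by 3.35, and AT4G27280, an EF-hand calcium-binding protein, by 3.35. All 10 were higher after inoculation in 27 of 27 pairs, with adjusted p between 1.12e-29 for AT4G39670 and 1.79e-16 for AT1G26380.

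Among the named genes that fell, AT3G16370, a GDSL-type lipase gene, changed most, from a mean level of 7.53 to 4.61. It fell by 2.92 ± 0.13 (SE, adjusted p = 2.42e-23). The light-regulated gene CCL (AT3G26740) fell by 2.52 ± 0.14 and AT3G18050 fell by 2.34 ± 0.14. TUB6 (AT5G12250), a beta-tubulin gene, fell by 1.63, COR47 (AT1G20440), a cold-induced dehydrin gene, fell by 1.62, and ATHM2 (AT4G03520), a chloroplast thioredoxin gene, fell by 1.55. The remaining 4 of the 10 were AT2G19310, a small heat shock protein gene, which fell by 1.48, LHCB4.3 (AT2G40100), of the light-harvesting antenna, which fell by 1.4, AT2G39710, of the aspartyl protease family, which fell by 1.3, and AT2G04700, a ferredoxin-thioredoxin reductase subunit gene, which fell by 1.26. Between 24 and 27 of the 27 pairs went down for each of these 10 genes.

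Of the 14 gene lists fixed before the data were examined, 2 had at least 3 measured members. All 3 measured genes of the salicylic acid list rose, over all genes tested and adjusted over the list alone: UGT76B1 and GRX480 as above and WRKY53 by 0.79 ± 0.18 (adjusted p = 0.000155), with a list median of 4.41 (fry, adjusted p = 6.38e-22). WRKY53 was higher in 19 of 27 pairs, and was at -0.03 (adjusted p = 0.875) when each array was centred on its median and at 0.16 (adjusted p = 0.373) after quantile normalization. All 4 measured genes of the early immune signalling list rose, again also adjusted over the list alone: the zinc finger gene STZ (AT1G27730) by 2.24 ± 0.12, WRKY29 by 2.20 ± 0.15, WRKY6 by 2.1 ± 0.20 and WRKY22 by 1.46 ± 0.19, with a median of 2.15 (fry, adjusted p = 3.59e-17). Tested against the other genes of the array with camera, both lists had an adjusted p = 0.328 with an estimated correlation and 0.122 with the preset one. Single measured genes stood for 5 other lists. GSTF3 (AT2G02930), a glutathione S-transferase gene, rose by 2.99 ± 0.23, and AT2G04400, indole-3-glycerol phosphate synthase of tryptophan synthesis, rose by 2.88 ± 0.09. The defensin gene PDF1.2 (AT5G44420) rose by 0.59 ± 0.20 (adjusted p = 0.00755) and was at -0.23 with centred arrays and at -0.26 after quantile normalization, neither past the threshold. Without set 1 its difference was 0.49 (adjusted p = 0.0978). COR47 fell, as given above. The elongation factor gene EF1A (AT5G60390), the only reference gene measured, differed by -0.06 ± 0.09 (adjusted p = 0.549), with levels of 8.64 ± 0.31 (SD, n = 27) in mock and 8.58 ± 0.34 (SD, n = 27) in inoculated arrays. Its difference was 0.16 in set 1, -0.43 in set 2 (adjusted p = 0.0312) and 0.098 in set 3, and it was -0.87 (adjusted p = 2.20e-10) with centred arrays and -1.01 (adjusted p = 2.39e-09) after quantile normalization. The other 7 lists, among them photosynthesis, the circadian clock and markers of other leaf cell types, had no named probe.

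Further groups were formed from the gene names after the probe annotation was read. All 5 chloroplast protein genes fell, by 0.43 for AT1G09130 to 1.55 for ATHM2 (median -1.26; fry, adjusted p = 2.1e-22; camera with an estimated correlation, adjusted p = 0.00534). All 3 chitinase genes rose, CHI by 3.5, AT2G43620 by 2.17 and AT4G01700 by 1.39 (median 2.17; fry, adjusted p = 6.24e-18; camera with an estimated correlation, adjusted p = 0.710). Of 5 EF-hand genes, 4 rose, among them AT5G39670 by 3.05 and AT2G41410 by 2.01, and AT2G41090 was at -0.21 ± 0.17 (adjusted p = 0.248). Of 6 heat shock and chaperone genes, 5 rose and AT2G19310 fell, and of 7 UDP-glycosyltransferase genes 4 rose. By fry the EF-hand group had an adjusted p = 2.48e-16, the heat shock group 1.12e-19 and the glycosyltransferase group 7.08e-19, and each had an adjusted p = 0.717 by camera with an estimated correlation. The 3 class III peroxidase genes rose, by 2.74 for AT5G64120 but by only 0.55 and 0.39 for AT5G19890 and AT2G37130, and their median was -0.27 (adjusted p = 0.826) with centred arrays.

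In this fit 366 genes were higher and 113 lower after inoculation at an adjusted p under 0.05, which is 76.4% higher among those called. The split depended on scaling. The median of all probes rose by 0.54 in the deposited values, and centring each array on its median gave 212 higher and 295 lower (41.8% higher, median of all probes -0.27). Quantile normalization gave 221 and 275 (44.6% higher, median -0.17), and setting each array to EF1A gave 353 and 97 (78.4% higher, median 0.60). Centring takes the middle of each array as unchanged, and quantile normalization its whole range of levels. An array of chosen genes need not meet either condition, and EF1A scaling rests on 1 gene. Which scaling is right could not be settled from these values. Within the sets taken alone, 306 genes were higher and 90 lower in set 1, 324 and 104 in set 2, and 328 and 96 in set 3.

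Each accession was then tested for its own response. Col-0 had 297 genes higher and 74 lower, the largest total of the 9 accessions, followed by Mt-0 with 270 and 78 and Est-1 with 256 and 76. Tsu-1 had 247 and 62, Kin-0 227 and 56, Kas-1 226 and 81, Ws-2 225 and 56, Cvi-1 212 and 59, and Ler-0 203 and 55. UGT76B1 was higher in all 9, by 3.14 in Kas-1 to 6.81 in Mt-0, and GRX480 by 3.84 in Kas-1 to 5.26 in Ws-2. In all 9 accessions 121 genes were past the threshold upwards and 26 downwards. Across genes, which are not independent replicates, the responses of accession pairs had a correlation of 0.71 for Est-1 and Kin-0, the lowest, to 0.95 for Mt-0 and Tsu-1, the highest. Such counts do not compare accessions, which the tests of differences below do. Without set 1 the Kas-1 total of 307 became 204.

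**Figure D1:**
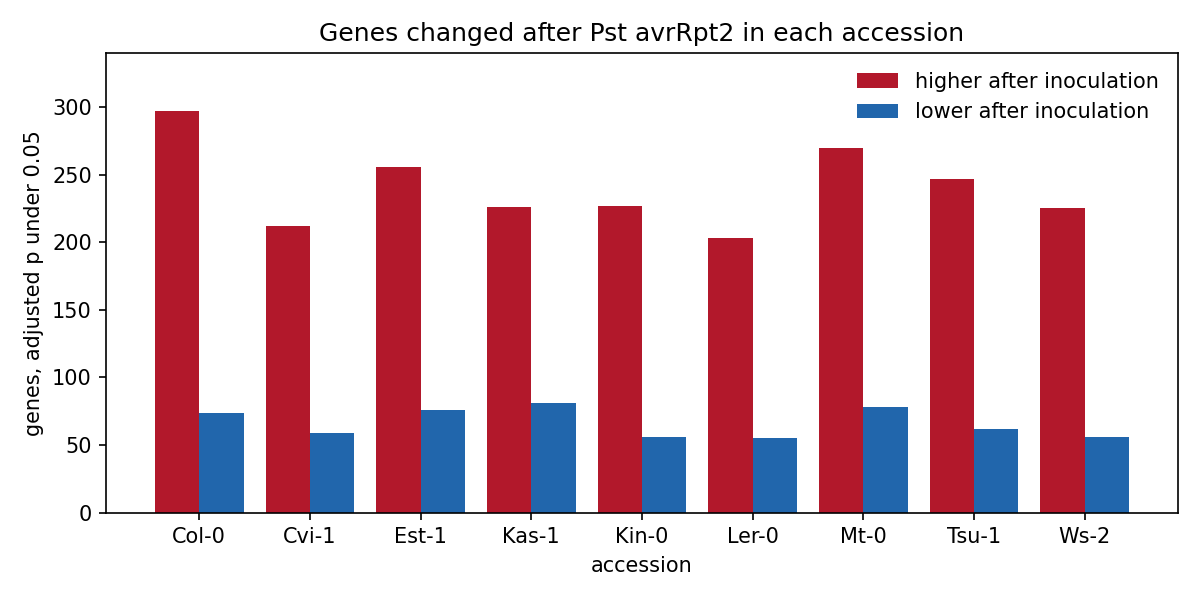
Number of genes (y axis) past an adjusted p of 0.05 in each accession (x axis), with red bars for genes higher and blue bars for genes lower after inoculation, out of 575 probes tested. Higher genes ran from 203 in Ler-0 to 297 in Col-0, and lower genes from 55 in Ler-0 to 81 in Kas-1.

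How strongly each accession ran the common response was summarised as a slope on the mean response of the other 8 accessions, in each set. Col-0 had the largest response size, 1.44 ± 0.07 (SD, n = 3), and Mt-0 the next, 1.22 ± 0.09. Tsu-1 was at 1.02 ± 0.20, Est-1 at 0.92 ± 0.12, Ws-2 at 0.91 ± 0.22, Cvi-1 at 0.90 ± 0.05, Kin-0 at 0.89 ± 0.09, Ler-0 at 0.82 ± 0.11 and Kas-1 at 0.80 ± 0.23. The accessions differed (permutation test within sets, 100000 resamples, p = 0.0032). Pairs of accessions were not tested, because 3 values against 3 give an exact p of at least 0.1.

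**Figure D2:**
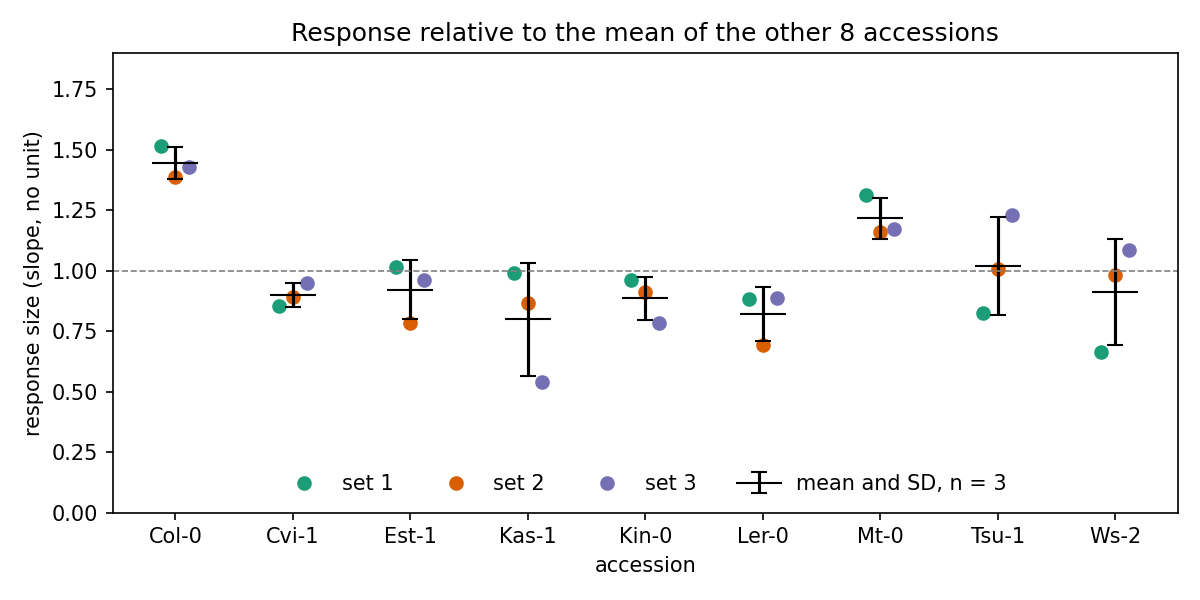
Response size (y axis, a slope without unit, 1 being the mean of the other 8 accessions) for each accession (x axis), with coloured points for the 3 sets and black bars for mean and SD. The Col-0 points lie between 1.39 and 1.52, above every other point, of which the highest is Mt-0 in set 1 at 1.31.

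The response of 156 genes differed among the accessions (moderated F-test, adjusted p under 0.05), and of 248 with the set as a replicate block. Without set 1 the count was 57, without set 2 it was 59, and with each array set to EF1A 72. The named gene with the largest F was AT2G19310, which fell by 3.10 in Mt-0 and was at -0.09 in Kas-1, a range of 3.01 (adjusted p = 4.34e-07). The AAA-type ATPase genes AT3G28540 and AT3G28510 came next. AT3G28540 was at 2.42 in Col-0 and at -1.06 in Kas-1 (adjusted p = 1.65e-06), and AT3G28510 was at 3.77 in Cvi-1 and at -0.13 in Kin-0 (adjusted p = 4.16e-06). AT2G04400 rose by 4.40 in Col-0 and by 1.61 in Ws-2. The small heat shock protein gene AT2G29500 rose by 3.22 in Col-0 and was at 0.03 in Kin-0, and Hsp70-2 rose by 6.48 in Col-0 and by 3.2 in Kin-0. AT5G52760, a heavy metal-associated domain protein gene, rose by 4.37 in Col-0 and by 1.31 in Est-1. The beta-glucosidase gene BGLU45 (AT1G61810) rose by 3.3 in Kas-1 and was at 0.55 in Kin-0. AT2G14290 was at 2.90 in Kas-1 and -0.14 in Ler-0, and AT3G28270 was at -2.04 in Kin-0 and 0.14 in Ws-2. Without set 2 the adjusted p of AT5G52760 was 0.0727 and that of BGLU45 0.0517.

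**Figure D3:**
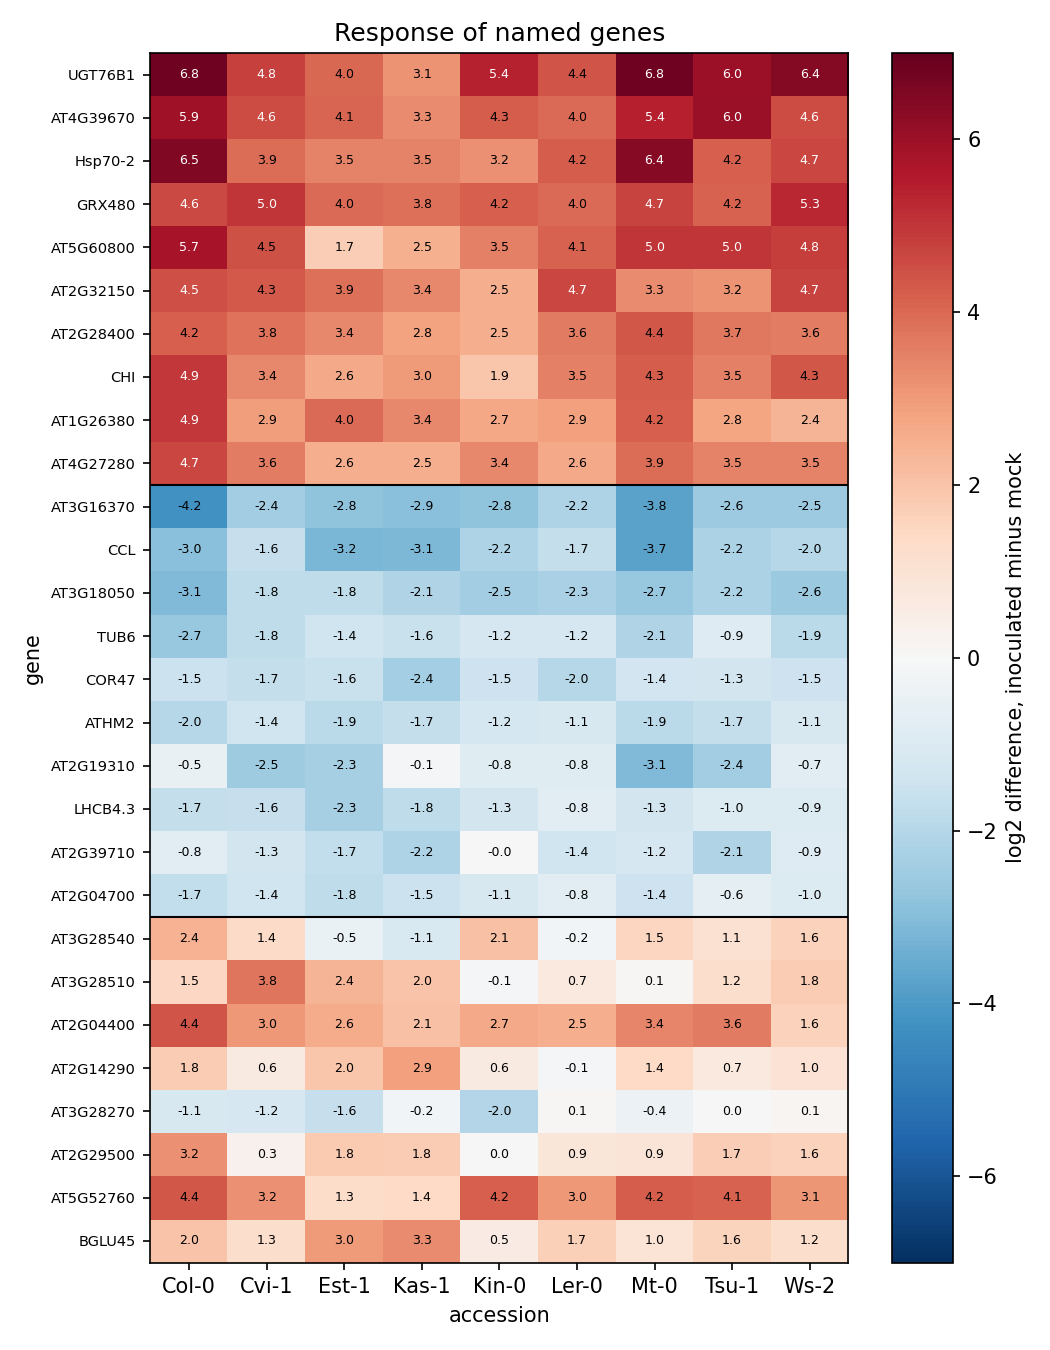
Log2 difference between inoculated and mock arrays (colour and printed value) for named genes (rows) in the 9 accessions (columns). From top to bottom, separated by lines, are the 10 largest rises, the 10 largest falls and the further genes whose response differed most among accessions. UGT76B1 ranges from 3.14 in Kas-1 to 6.81 in Mt-0, and AT3G28540 from -1.06 in Kas-1 to 2.42 in Col-0.

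Set against the mean of the other 8, Col-0 stood out by stronger responses in the deposited values. In Col-0, 89 genes had a higher and 8 a lower difference than in the others. A lower difference can be a smaller rise or a larger fall, and a higher one a larger rise or a smaller fall. Of the 89 genes, 87 were called higher in the mean response, and of the 8, 0 were. Hsp70-2 exceeded the others by 2.29 ± 0.46 (SE, adjusted p = 0.000728), GSTF3 by 2.21 ± 0.73 (adjusted p = 0.0316) and AT2G29500 by 2.09 ± 0.34 (adjusted p = 3.13e-05). The GSTF3 difference was past the threshold in 6 of 11 alternatives. The 89 genes had a median mock level 0.82 below the others (-0.82) and a median inoculated level 0.72 above them. Without set 1 the Col-0 total of 97 became 32, without set 2 it became 35, with each array set to EF1A 53, and after quantile normalization 61. With centred arrays 42 of the 89 were called in the same direction, and after quantile normalization 36. The counts with a higher and a lower difference in Col-0 were then 42 and 31 with centred arrays and 36 and 25 after quantile normalization, so the split depended on scaling. In Mt-0, 5 genes had a higher and 4 a lower difference (21 in all with the set as a replicate block). Among them were Hsp70-2, at 2.16 ± 0.46, AT2G19310, at -1.82 ± 0.32, and AT3G28510, at -1.56 ± 0.39. AT2G19310 fell further in Mt-0 than in the others on average, so its lower difference is not a weaker response. The Mt-0 total of 9 became 3 without set 1, 5 without set 2, 5 with each array set to EF1A and 15 with centred arrays. Its Hsp70-2 call was lost without set 1 or set 2, that of AT3G28510 when any of the 3 sets was left out, and those of AT3G28510 and AT2G19310 with each array set to EF1A.

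Kin-0 differed in both directions, with 29 genes higher and 28 lower, and 102 in all with the set as a replicate block. AT2G43620, a chitinase family gene, exceeded the others by 2.63 ± 0.58 (SE, adjusted p = 0.00195) and AT2G41090, an EF-hand gene, by 2.16 ± 0.54 (adjusted p = 0.00577). AT1G05340 was at -2.32 ± 0.37 (adjusted p = 0.000145), with a rise of 1.21 in Kin-0 against 4.36 in Mt-0. The 28 genes with a weaker response had a median inoculated level of -1.69 relative to the others and a median mock level of -0.10. The total of 57 became 12 without set 1 and 28 without set 2, 23 with each array set to EF1A, and 97 with centred arrays. The AT2G43620 call was lost without set 1 or set 2, and the AT2G41090 call without set 2.

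In Est-1 and Kas-1 the genes with lower differences had higher mock levels on the arrays used to choose them. In Est-1, 24 genes had a higher and 32 a lower difference (88 in all with the set as a replicate block), and in Kas-1 8 and 33 (78 with the block). Of the lower ones, 26 of 32 in Est-1 and 27 of 33 in Kas-1 were called higher in the mean response. AT5G60800 was at -2.69 ± 0.50 in Est-1 (adjusted p = 0.000465), with a mock level of 4.90 against 2.61 in Col-0, and AT2G41090 was at -2.17 ± 0.53 there. AT4G24340 went the other way in Est-1, with an excess of 2.46 ± 0.41. In Kas-1, UGT76B1 was at -2.43 ± 0.73, AT3G28540 at -2.24 ± 0.38 and AT5G52760 at -2.04 ± 0.42 relative to the others. The mock level of AT3G28540 was 2.29 ± 0.27 higher in Kas-1 (adjusted p = 5.93e-09), and its inoculated level differed by 0.05 ± 0.27 (adjusted p = 0.923). The median mock excess was 1.16 over the 32 Est-1 genes and 1.19 over the 33 Kas-1 genes. Their median inoculated level was -0.65 relative to the others in Est-1 and -0.29 in Kas-1, with 12 genes called lower in each. For genes chosen in 2 sets, the excess in the left-out set was between 0.72 and 1.32 in Est-1 and between 0.12 and 2.33 in Kas-1, the lowest being 0.271 of that in the choosing sets. In that case, Kas-1 in set 2, the inoculated level was at -1.15. Leaving out set 1, 2 or 3 gave totals of 27, 14 and 27 in Est-1 and of 18, 11 and 14 in Kas-1. With each array set to EF1A the totals were 20 in Est-1 and 7 in Kas-1, and the calls of AT2G41090 in Est-1 and AT5G52760 in Kas-1 were lost. Without set 2 the calls of AT5G60800 and AT2G41090 in Est-1 and of AT5G52760 in Kas-1 were lost, and without set 3 that of AT2G41090. Without the Kas-1 mock array of set 3 the Kas-1 total of 41 became 25, and the UGT76B1 call was lost there and in 5 of the other 10 alternatives.

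The other 4 accessions differed in at most 9 genes each, which was also the Mt-0 total. Cvi-1 had 3 higher and 2 lower (17 with the set as a replicate block), and AT3G28510 exceeded the others by 2.59 ± 0.39 (adjusted p = 1.93e-05). Ws-2 had 7 and 2 (16 with the block), with AT2G04400 at -1.42 ± 0.28 and UGT84A3 (AT4G15490), a hydroxycinnamate glucosyltransferase gene, at 1.18 ± 0.31, which was past the threshold in 6 of 11 alternatives. Ler-0 had 1 and 5 (1 in all without set 1 or without set 2), with AT2G14290 at -1.51 ± 0.32, and Tsu-1 had 0 and 1 by limma, with 26 genes at an unadjusted p under 0.05 and 3 genes with the block. Without set 1, 2 or 3 the lowest totals were 2 in Cvi-1 and 1 in Ws-2, and Tsu-1 had at most 2. With each array set to EF1A there were 2 in Ler-0 and 3 in Ws-2. The calls of AT2G04400 in Ws-2 and of AT2G14290 in Ler-0 were lost without set 1 or set 2, and that of AT2G14290 also with EF1A and after quantile normalization. Tested as lists, neither the salicylic acid nor the early immune signalling list was past the threshold in any accession against the other 8 (fry, 0 of 18 tests past the threshold, 3 at an unadjusted p under 0.05, smallest adjusted p = 0.187). Single members were called only in the salicylic acid list, 1 of 3 in Col-0 and 1 of 3 in Kas-1.

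Mock leaves also differed among accessions, in 282 genes (moderated F-test). The largest differences were in AT2G25450, a 2-oxoglutarate-dependent dioxygenase gene known as GSL-OH that hydroxylates an alkenyl glucosinolate. Its mock level was 12.71 in Kin-0, 9.85 in Est-1, 9.76 in Col-0, 9.73 in Mt-0 and 8.74 in Ws-2, against 4.29 in Tsu-1, 3.59 in Kas-1, 2.91 in Cvi-1 and 2.47 in Ler-0, a range of 10.23 (adjusted p = 5.69e-20). CHI was at 7.62 in Kas-1 and 7.31 in Est-1, and between 2.86 and 4.55 in the other 7. AT3G28540 ran from 2.71 in Col-0 to 6.24 in Kas-1, and AT2G19310 from 3.12 in Kas-1 to 6.60 in Col-0. AT2G04400 ran from 3.86 in Tsu-1 to 6.29 in Kas-1, AT3G13950 from 1.94 in Mt-0 to 5.04 in Kas-1, AT2G18210 from 1.78 in Kin-0 to 4.55 in Ler-0, and AT3G28270 from 1.95 in Ws-2 to 4.51 in Kin-0. AT5G15610 was at 1.91 in Kas-1 and between 3.43 and 3.83 elsewhere. AT5G41950 was at 2.50 in Cvi-1 and 2.56 in Tsu-1 and between 3.53 and 4.02 elsewhere. A probe that matches the sequence of some accessions less well reads lower there in both treatments.

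**Figure D4:**
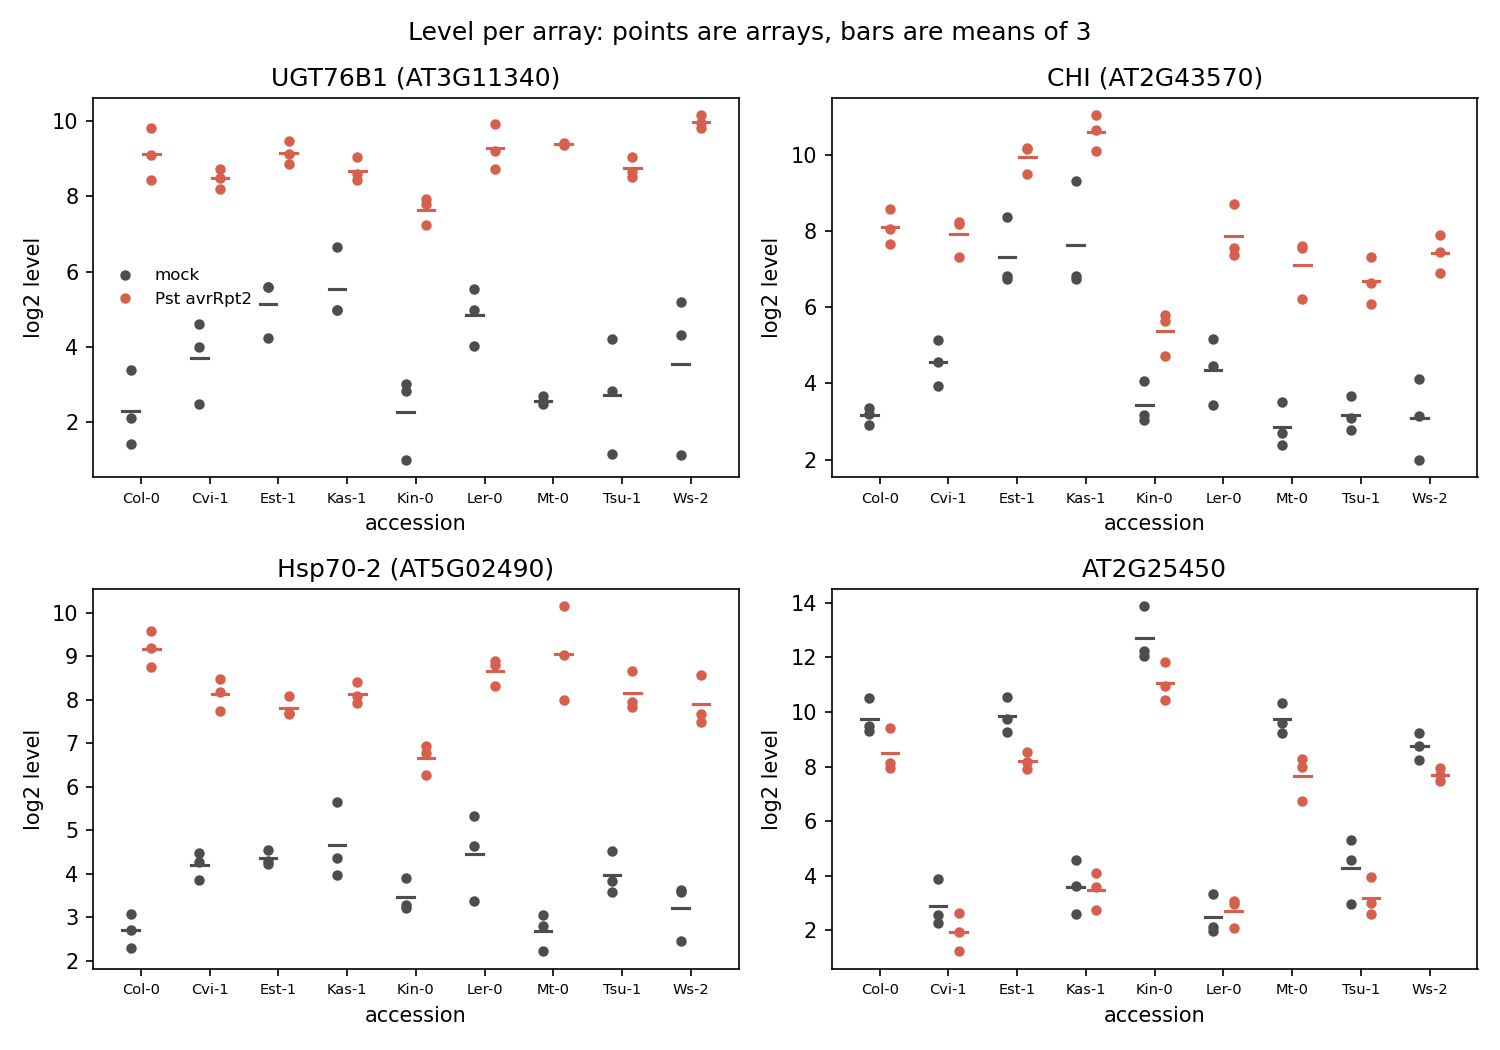
Log2 level (y axis) of UGT76B1, CHI, Hsp70-2 and AT2G25450 in each accession (x axis), with grey points for mock and red points for inoculated arrays and bars for the means of 3 arrays. Mock CHI is near 7.62 in Kas-1 and 7.31 in Est-1 and at most 4.55 in the means of the others, and the mock means of AT2G25450 are at most 4.29 in Cvi-1, Kas-1, Ler-0 and Tsu-1 and at least 8.74 in the others.

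After this F-test had been seen, each accession's mock level was set against the other 8. Kas-1 had 180 genes higher and 38 lower, Est-1 114 and 33, and Col-0 23 higher and 110 lower. The salicylic acid list was higher in mock leaves of Kas-1 (median 1.83; fry, adjusted p = 0.000674), Est-1 (1.35, adjusted p = 0.00257) and Ler-0 (1.2, adjusted p = 0.0233). It was lower in Col-0 (-1.48, adjusted p = 0.00257), Mt-0 (-1.19, adjusted p = 0.0115) and Kin-0 (-0.90, adjusted p = 0.0301, and 0.115 with centred arrays). The early immune signalling list was past the threshold in no accession. Its smallest adjusted p was that of Kas-1 (median 0.51, adjusted p = 0.0539), which was 0.0210 with the set as a replicate block and 0.708 with centred arrays. Without the Kas-1 mock array of set 3 the Kas-1 counts were 92 and 24. With centred arrays they were 99 and 130, those of Est-1 70 and 144, and those of Col-0 84 and 34, so that the direction of these counts depended on scaling.

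In the values as deposited, accessions with a higher mock level of the 3 measured salicylic acid list genes, of 28 listed, had a smaller response size. The mean level of UGT76B1, GRX480 and WRKY53 in mock arrays ran from 2.11 in Col-0 to 4.91 in Kas-1. Over the 9 accessions Pearson's r was -0.713 (exact permutation test, two-sided, p = 0.0211) and Spearman's rho -0.717 (exact permutation p = 0.0369). Without Kas-1 and Est-1, the 2 accessions farthest from the median in list level, r was -0.741. Col-0 and Mt-0, with the lowest list levels and the largest response sizes, stayed in, and r was not computed without them. The rho was not past the threshold without set 2 (-0.633, exact permutation p = 0.0760) or without set 3 (-0.600, exact permutation p = 0.0968). Without set 3, r was -0.165 once the 2 accessions then farthest from the median were left out, so there the relation rested on those accessions. This was the only relation across accessions that was computed. It was not recomputed with centred arrays, after quantile normalization, with EF1A scaling or without the Kas-1 mock array of set 3. Mock arrays enter both measures. With the list level from 1 set and the response size from the other 2, r was -0.754 (exact permutation p = 0.0175, and r = -0.398 without the 2 accessions farthest from the median) for set 1, -0.518 (p = 0.155) for set 2 and -0.280 (p = 0.466) for set 3, so the relation was not past the threshold in 2 of 3 such splits.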

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

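The 3 patterns weighed here were chosen after the counts had been seen, and the tests of each were set down before their results were computed. Hsp70-2 rose by 6.48 in Col-0 and 3.2 in Kin-0, and the response of 156 genes differed among the 9 accessions. In 99 shuffles of the accession labels within sets the highest other count was 0. In that fit, differences in mock level between shuffled accessions add to the spread and hold shuffled counts down. With the pair as a replicate block, where these differences cancel, the count was 211 and the highest other 4. Chance is excluded there at this resolution (1 of 100 splits as large, the real one included). The response size differed too (permutation p = 0.0032).

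In Est-1 and Kas-1, genes with a weaker response had a higher mock level, by a median of 1.16 over 32 genes and 1.19 over 33. A shift of all probes on the mock arrays is argued against, since 89 genes without a response had a median excess of 0.00 in Est-1 and 0.05 in Kas-1, a ratio of at most 0.0382. Over all 575 probes the median mock excess was 0.14 in Est-1 and 0.32 in Kas-1, and the check does not cover probes of genes that respond. The part played by the Kas-1 mock array of set 3 stays open. The excess without it was 0.97, a ratio of 0.812, but the other Kas-1 mock arrays also chose these genes. Without it 16 genes had a lower difference, 11 of them among the 33. Kas-1 genes chosen in the other 2 sets had an excess of 0.79 in set 1 (14 genes) and 0.12 in set 2 (7 genes). Noise of the mock arrays, which enters both measures, stays open. For genes chosen in 2 sets, the excess in the left-out set was compared with that in the choosing sets. Its ratio was 0.515, 1.42 and 0.939 in Est-1 and 0.466, 0.271 and 1.32 in Kas-1. The bound against noise was a ratio over 0.5 in every case, which only Est-1 met. An accession difference in basal level may also account for it: the mock level was past the threshold for 23 of the 32 and 23 of the 33 genes, but on arrays that also chose them.

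In Col-0, 89 genes had a higher difference than in the other 8, 87 of them called higher in the mean response. On the values as deposited, probes that match Col-0 better are argued against as the whole cause. Genes chosen in 2 sets were lower in Col-0 mock arrays of the left-out set, with a highest median of -0.692. That check was not repeated with centred arrays, although mock levels relative to the other accessions depend on scaling. The Col-0 response size stayed between 1.38 and 1.46 in 6 alternatives, centring and quantile normalization among them. For the gene count, scaling of the Col-0 arrays stays open. With centred arrays 42 genes remained, a ratio of 0.472, between the bounds set for either reading, and 31 genes then had a lower difference against 8 as deposited. Of those 8, 0 were called higher in the mean response, so a lower difference there is not a smaller rise. An accession difference in the response may account for the rest and was not tested.

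In Kin-0, 28 genes with a lower difference, 27 of them called higher in the mean response, reached a lower level after inoculation, with a median of -1.69. Noise of the inoculated arrays is argued against, since genes chosen in 2 sets kept at least 0.726 of their deficit in the left-out set. Probes that match Kin-0 worse cannot be told apart from a weaker response. The ratios of mock to inoculated deficit were 0.157, -0.651 and 0.264, on 3, 6 and 8 genes. The negative one came with a mock level 0.30 higher in Kin-0, and the highest was close to the bound of 0.25. An accession difference may account for it and was not tested.

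Counts of genes whose response differed from the other 8 were 97 in Col-0, 5 in Cvi-1, 56 in Est-1, 41 in Kas-1, 57 in Kin-0, 6 in Ler-0, 9 in Mt-0, 1 in Tsu-1 and 9 in Ws-2. In 99 shuffles each, the highest other counts were, in the same order, 1, 0, 2, 2, 1, 0, 1, 1 and 1. In the accessions other than Tsu-1 no shuffle reached the real count. These shuffles used the fit without pairs, where differences in mock level hold shuffled counts down. They were not repeated with the pair as a replicate block, so by themselves they do not exclude chance for a single accession. For Tsu-1 shuffles did reach the real count of 1, and 3 of 100 splits, the real one included, gave at least 1, so that a single gene there carries little weight.

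Among the genes whose response differed most, the range over accessions was 3.01 for AT2G19310, 3.49 for AT3G28540, 3.90 for AT3G28510, 2.79 for AT2G04400, 3.03 for AT2G14290, 2.19 for AT3G28270, 3.19 for AT2G29500, 3.06 for AT5G52760, 3.28 for Hsp70-2 and 2.76 for BGLU45. Relative to the other 8, Col-0 differed by 2.29 in Hsp70-2, 2.21 in GSTF3 and 2.09 in AT2G29500, and Cvi-1 by 2.59 in AT3G28510. Est-1 differed by -2.69 in AT5G60800, 2.46 in AT4G24340 and -2.17 in AT2G41090. Kas-1 differed by -2.43 in UGT76B1, -2.24 in AT3G28540 and -2.04 in AT5G52760. Kin-0 differed by 2.63 in AT2G43620, -2.32 in AT1G05340 and 2.16 in AT2G41090, and Ler-0 by -1.51 in AT2G14290. Mt-0 differed by 2.16 in Hsp70-2, -1.82 in AT2G19310 and -1.56 in AT3G28510, and Ws-2 by -1.42 in AT2G04400 and 1.18 in UGT84A3.

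For the mean response, 479 genes were called, against at most 19 in 99 shuffles of treatment within accessions, and chance is excluded. For mock levels, 282 genes were called against at most 128 in 99 shuffles, and chance is excluded. Within an accession, 3 arrays against 3 make 10 splits, too few for a share under 0.05. The real and highest other counts were 371 and 1 in Col-0, 271 and 0 in Cvi-1, 332 and 0 in Est-1, 307 and 118 in Kas-1, 283 and 0 in Kin-0, 258 and 0 in Ler-0, 348 and 0 in Mt-0, 309 and 1 in Tsu-1, and 281 and 29 in Ws-2. Among the 4 splits that part all 3 pairs, the highest other in Kas-1 was 34.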

How the results depend on the processing

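The alternatives without the Kas-1 mock array of set 3, with the groups formed by gene name, with the list level and response size from separate sets, and with single accessions' mock levels were chosen after seeing the data. Counts of genes that differ between accessions depended most on the processing, and the cause was not tested. Of 68 results on single named genes, 50 kept their call in all settings. Of 815 recomputed values, 759 kept sign and call, 47 were no longer past the threshold, 3 passed it and 6 changed sign. The counts within accessions stayed within 1.5 times, apart from Kas-1 without set 1. The response sizes moved by less than the spread between sets with centred arrays, after quantile normalization and over genes with a larger mean response. They were not computed with EF1A scaling. With each set left out they also moved by less, but a mean of 3 values could hardly do otherwise. That of Kas-1 then ran from 0.69 to 0.97. Signal over background is not known from the values used here, so its limit was not tested. Averaging probes, a pseudocount and PR1 alone were not run, since each gene has 1 probe, the values are logs and PR1 is not named.

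With each array centred on its median, the mean response had 212 genes higher and 295 lower, PDF1.2 was at -0.23, WRKY53 at -0.027, the class III peroxidases at -0.27 and the vacuolar ATPase genes at -0.63, and the aspartyl protease genes had a median of 0.24 with a test direction down. The differences from the other 8 numbered 97 in Kin-0, 15 in Mt-0 and 2 in Tsu-1. With quantile normalization the mean response had 221 and 275, PDF1.2 was at -0.26, the vacuolar ATPase genes at -0.81 and the aspartyl protease genes at 0.28 with a test direction down, and the differences numbered 61 in Col-0 and 2 in Tsu-1. With each array set to EF1A, 72 genes differed among accessions, and 53 in Col-0, 20 in Est-1, 7 in Kas-1, 23 in Kin-0, 2 in Ler-0, 5 in Mt-0 and 3 in Ws-2 differed from the other 8. Without the probes with the lowest mean levels there were 3 in Cvi-1 and 3 in Ler-0.

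With the set as a replicate block, 248 genes differed among accessions, and 17 in Cvi-1, 88 in Est-1, 78 in Kas-1, 102 in Kin-0, 21 in Mt-0, 3 in Tsu-1 and 16 in Ws-2. With the pair as a replicate block there were 8 in Cvi-1, 89 in Kin-0, 11 in Ler-0, 15 in Mt-0 and 16 in Ws-2. Camera left the median of the salicylic acid list at 4.41 and of the early immune list at 2.15, with an adjusted p = 0.122 for both with the preset and 0.328 with an estimated correlation.

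Leaving out each set in turn, with fewer arrays, gave 57 to 123 genes that differed among accessions. Against the other 8 it gave 32 to 78 in Col-0, 2 to 4 in Cvi-1, 14 to 27 in Est-1, 11 to 18 in Kas-1, 12 to 42 in Kin-0, 1 to 5 in Ler-0, 3 to 8 in Mt-0, 1 to 2 in Tsu-1 and 1 to 6 in Ws-2. The Kas-1 response had 204 to 310 genes over left-out sets and arrays. Without the Kas-1 mock array of set 3, 25 genes differed in Kas-1 from the other 8. EF1A (AT5G60390) was at 0.16 in set 1 alone, 0.098 in set 3 alone and between -0.17 and 0.13 with each set left out in turn, none past the threshold. It was past the threshold at -0.43 in set 2 alone, -0.87 with centred arrays and -1.01 after quantile normalization. With the list level from set 2 or set 3, r was -0.518 and -0.280.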

Other observations

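Further groups formed from the gene names went in several directions. Of 4 aspartyl protease genes, AT3G51330 rose by 2.25, AT1G03220 by 1.63 and AT5G19110 by 0.48, and AT2G39710 fell by 1.3 (fry, adjusted p = 1.85e-09; camera with an estimated correlation, adjusted p = 0.984; direction down with centred arrays, adjusted p = 0.285). All 5 WRKY and zinc finger genes rose, with a median of 2.1 (fry, adjusted p = 2.61e-15; camera with an estimated correlation, adjusted p = 0.717). Of 3 histone H3 genes 2 fell, AT4G40030 by 1.09 and AT1G09200 by 0.27 (fry, adjusted p = 3.49e-07; camera with an estimated correlation, adjusted p = 0.562). AT1G09200 was close to the threshold (limma, adjusted p = 0.0499), and adjusted over the group alone only 1 gene was past it.

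Of 5 sulfur and glucosinolate genes, UGT74B1 rose by 0.89, AT2G25450 fell by 1.06 and GTR1 fell by 0.24, and of 6 respiratory chain genes SDH1-1 rose by 0.90 and 3 fell. Adjusted over each group alone, 2 genes were past the threshold in the first and 2 in the second. Neither group passed fry (adjusted p = 0.790 and 0.0817), but the respiratory chain group did with the set as a replicate block (adjusted p = 0.0100). With centred arrays both were past the threshold downwards by fry (adjusted p = 7.26e-14 and 5.44e-15). By camera with an estimated correlation, on the values as deposited, each had an adjusted p = 0.562. Of 3 vacuolar ATPase genes, 2 rose by at most 0.20 (fry, adjusted p = 0.108), and with centred arrays the group was down by fry (adjusted p = 2.34e-12). Camera with an estimated correlation, on the values as deposited, gave it an adjusted p = 0.717. Relative to the other 8, the heat shock and chaperone group responded more strongly in Col-0, with a median of 1.38 and 5 of 6 genes called (fry, adjusted p = 5.14e-07). The same group responded more weakly in Cvi-1, with a median of -0.72 and 0 of 6 genes called (adjusted p = 0.0186). The UDP-glycosyltransferase group responded more strongly in Col-0, with a median of 0.75 and 2 of 7 genes called (adjusted p = 0.0125, and 0.399 with centred arrays). Of 108 such tests, on 12 groups in 9 accessions and chosen after seeing the data, these 3 were past the threshold. With the set as a replicate block 14 were, these 3 among them, and with centred arrays 12 were, so the number of calls depended on both choices. The smallest adjusted p among the 11 others was that of the chitinases in Col-0 (median 1.62, adjusted p = 0.00745 with the block and 0.0527 without).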
